A study of Homo sapiens with 8 samples.

How the data were processed

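Small RNA sequencing libraries were made from MEC-1 cells, an established B-cell line derived from chronic lymphocytic leukaemia, and from exosomes, small membrane vesicles released by those cells into the culture medium. Per the labels' protocols, the cells were grown in bioreactors, vesicles were pelleted from the supernatant at 100000 g and floated on a 20% iodixanol cushion, RNA was taken with a column kit, and 30 ng of RNA under 200 nt went into an adapter-ligation small RNA kit with 15 cycles of PCR. The serum was depleted of exosomes, except in the upper medium compartment of the bioreactor, per the labels' protocols. There were 5 exosome libraries and 3 cell libraries. The design text states that 3 of the exosome samples have paired cell samples without naming them, and nothing used here says that the replicates came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

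The deposited values are raw read counts per feature, per the file headers, which are those of featureCounts. The submitters' processing notes name cutadapt 1.1, STAR, featureCounts and DESeq2 1.8.2 and the GRCh37 (hg19, hs37d5) genome build. The settings for reads that map to several places are not given in the sources used here. Each table holds 2709 non-coding RNA features with GRCh37 coordinates. Whether reads of near-identical genes were counted at each copy is not stated in the sources used here, and the deposited counts only show features with nearly the same values: 103 features fall into 37 groups whose counts lie within 2% or 5 reads of each other in every library, with up to 8 features in a group. Counting each group once removes 1.24% to 18.7% of a library's total, more in exosome than in cell libraries. Of the 2709 features, 624 have a number in place of a symbol, with lengths close to those of tRNAs, and 64 of these are in such groups; the files do not pair these numbers with names, and they are called tRNA-length features here. Some small RNAs have no feature of their own and lie within the span of a longer host gene. The span of GAS5, for instance, holds 10 such small RNAs. The counted part covers 72.9% of that span, and whether it holds these small RNAs was not checked.

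Symbols were matched to GENCODE release names in the reference tables, with 2024 of 2085 symbols found after older names were used. Printed coordinates are those of GRCh37. Only the placing of small RNAs within host genes used gene positions of the newer build, from RefSeq. Every feature was placed in 1 of 13 classes by its symbol or number. Total counts ran from 23353820 to 32436286 in exosome libraries and from 25675636 to 57323598 in cell libraries. Libraries carried no molecular identifiers, so intervals and floors cover counting error only.

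Exosome and cell libraries were compared with edgeR 4.0.16's quasi-likelihood test in R 4.3.3, with TMM scaling factors, the tool's default filter on low counts (10 counts as its minimum) and Benjamini-Hochberg adjustment; a feature was called at an adjusted p under 0.05. The standard error of a log2 fold change was its size divided by the square root of the F statistic. Fold changes are exosome over cell. A group total of 0 was replaced by a floor of 3 counts over the whole group to give a lower bound, and a total of 1 to 3 counts was given as a ratio of counts with its 95% exact binomial interval. Shares of reads per class and library diversity were compared with an exact permutation test, two-sided; 5 libraries against 3 give 56 splits and a smallest p of 0.0357. After adjustment over 13 classes a p under 0.05 needs at least 10 classes whose groups separate fully. For diversity, each library was thinned to 23353820 counts, the smallest total. miRNAs were also compared alone, with scaling from miRNAs only.

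Fixed before the data were examined were the tests, the alternatives tried, 25 gene lists and the rule for named genes. The lists were Y RNAs and their pseudogenes, vault RNAs, signal recognition particle RNAs, 7SK, the RNase P, RNase MRP and telomerase RNAs, major and minor spliceosomal snRNAs, C/D box and H/ACA box snoRNAs, small Cajal body RNAs, imprinted C/D snoRNAs, 5S and 5.8S rRNA, mitochondrial RNAs, let-7, the miR-17-92 cluster with its paralogs, B-cell and leukaemia-linked miRNAs, miRNAs often found in vesicle preparations, miRNA entries within other structured RNAs, and miRNAs of 6 other tissues as markers of foreign RNA. Lists with at least 3 tested members were tested with limma's camera at a preset correlation of 0.01, with camera at an estimated correlation, and with fry (limma 3.58.1). Named genes are the 10 with the largest change in each direction among those called, with a mean of at least 100 counts in the higher group and all libraries of the groups apart; the 5 most abundant in each group; all measured members of the Y, vault and RNase P, MRP and telomerase lists; and up to 4 of the most abundant members of every other list. Genes named outside this rule are said to be so.

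The count tests were checked on simulated data made from the real means and library sizes with 200 changed features: for exosome against cell libraries, 1182 simulated features passed edgeR's filter, 184 of them changed, and edgeR called 9.4% of features changed 2-fold, 29.5% of those changed 4-fold, 76.3% of those changed 8-fold and 0.3% of unchanged features. Apart from the changed features, raised and lowered alike, both simulated groups had the same means. Shifts of whole RNA classes, which scaling must handle in the real data, were therefore not simulated. Alternatives were DESeq2 (version 1.42.0) and limma-voom as tests, other scalings and filters, each library left out in turn, replicates 1 to 3 alone, and the replicate number as a block. Added after seeing the data were near-identical features counted once, a run without exosome 5 and cell 2, whose TMM factors were the lowest (0.524 and 0.552), and a run without the large rRNA features. Other work used Python 3.11.15 with NumPy, pandas and SciPy.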

Results

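Small RNA was sequenced from exosomes of the chronic lymphocytic leukaemia line MEC-1 (n = 5) and from the cells that release them (n = 3), in a series concerned with what such exosomes do to monocytes. The comparison asked which small non-coding RNAs exosomes carried relative to their cells of origin. Exosome libraries held 23353820 to 32436286 counts and cell libraries 25675636 to 57323598. Correlations of log2 CPM (counts scaled to library size times its TMM factor, so that a library's values need not add up to the same total) across features ran from 0.881 to 0.981 between exosome libraries, from 0.925 to 0.967 between cell libraries and from 0.739 to 0.882 between the groups; features are not independent replicates. The fitted biological coefficient of variation was 0.636 among exosome and 0.685 among cell libraries.

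Mean shares of several RNA classes differed between exosome and cell libraries, while rRNA took a large share of both. Y RNAs, small cytoplasmic RNAs bound by the Ro60 protein, took 15.0% ± 2.79 (SD, n = 5) of exosome reads and 1.28% ± 0.430 (SD, n = 3) of cell reads. C/D box snoRNAs, which guide 2'-O-methylation of rRNA in the nucleolus, took 1.79% ± 0.955 against 25.4% ± 5.54. Host genes took 2.91% ± 1.04 against 32.8% ± 4.48. Many of their spans hold snoRNAs or miRNAs without an entry of their own, which their counts may include. The share of rRNA was 50.2% ± 13.1 in exosomes and 27.1% ± 3.20 in cells, that of tRNA-length features 18.2% ± 6.93 and 2.30% ± 0.829, and that of miRNAs 7.10% ± 3.56 and 8.36% ± 3.32.

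In 8 of 13 classes every exosome library lay on the same side of every cell library: Y RNA, vault RNA, 7SL RNA, rRNA and tRNA-length features had higher shares in exosomes, and 7SK RNA, C/D box snoRNAs and host genes lower shares. The exact permutation test, two-sided, gave each of these p = 0.0357, the smallest that 5 against 3 libraries allow, and an adjusted p of 0.058, so no class share passed after adjustment over the 13 classes. The miRNA share (p = 0.571, adjusted p = 0.571) and the mitochondrial share (3.71% ± 3.17 against 1.17% ± 0.417, p = 0.214, adjusted p = 0.279) overlapped between groups in the same exact test. With near-identical features counted once, the tRNA-length share was 5.67% ± 3.06 in exosomes and 0.931% ± 0.318 in cells. Without the most abundant feature of each library, the rRNA difference was 9.54 percentage points in place of 23.1 and its groups overlapped (exact permutation p = 0.321, adjusted p = 0.348). The feature removed was each library's own, and held from 13.4% of reads in cell 3 to 51.4% in exosome 5. Shares were then of the remaining reads, so differences in this setting rest partly on how much each library lost. In the same exact test the groups of the mitochondrial share then separated fully (3.74 points, p = 0.0357, adjusted p = 0.058).

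**Figure D1:**
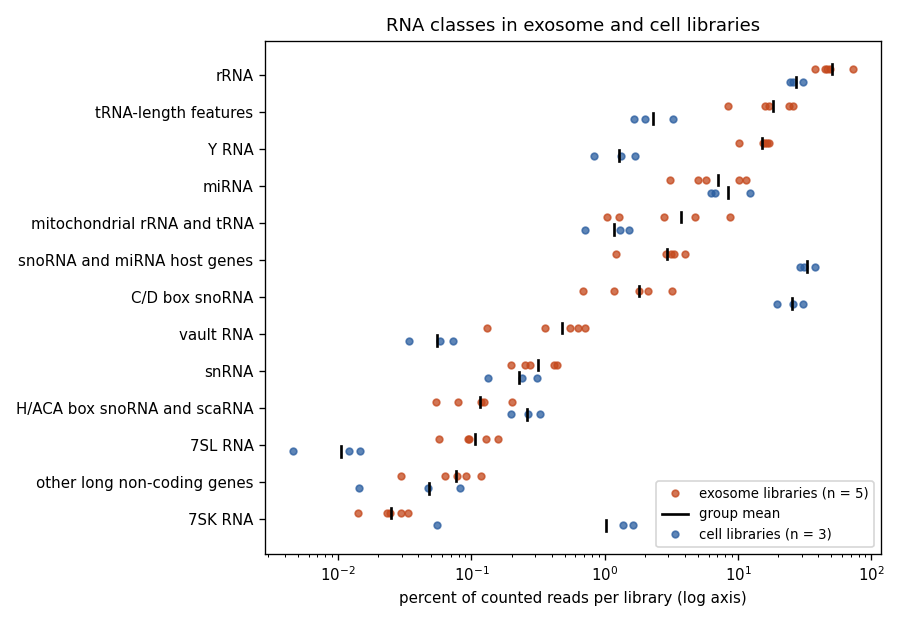
Percent of counted reads in 13 RNA classes, on a log axis, in each exosome library (orange, n = 5) and each cell library (blue, n = 3), with black bars at the group means. Exosome libraries held 15.0% Y RNA and 1.79% C/D box snoRNA on average, and cell libraries 1.28% and 25.4%.

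Of 1178 features tested, 241 were higher and 263 lower in exosomes, all by at least 2-fold, and 674 were not called by edgeR's quasi-likelihood test. The median log2 fold change of all features was -0.09, and 0.19 with scaling by total counts alone. The size of this shift differed between classes: the C/D box snoRNA median went from -2.732 to -2.275 and 7SK RNA from -5.391 to -5.348. The most abundant features of exosomes were RNA28S5, RNA5-8S5, RNY4, RNA18S5 and RNY1, and those of cells were RNA5-8S5, C17orf76-AS1, RNA28S5, GAS5 and SNHG5, the last through cell 2 alone (241550 CPM, against 8509 in cell 1 and 29606 in cell 3).

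All 4 Y RNAs rose in exosomes, and each was above the cell level in every exosome library. RNY4 (chromosome 7, 148660407 to 148660502, GRCh37) averaged 103930 ± 24737 CPM in exosomes and 6743 ± 2597 CPM in cells, a 15.4-fold difference (log2 3.95, SE 0.58, adjusted p = 0.000145). RNY5 was 26.1-fold higher (log2 4.71, SE 0.61), RNY3 6.19-fold and RNY1 4.35-fold (log2 2.76, without cell 3). The 3 genes of 7SL RNA, the RNA core of the signal recognition particle that directs proteins to the endoplasmic reticulum, also rose: RN7SL3 by 3.97, RN7SL1 by 3.22 and RN7SL2 by 3.05 on the log2 scale. The 7SL features are 297 to 300 nt long, above the size limit of the input RNA, so their reads stand for fragments. The vault RNAs of the VTRNA1 genes are components of the large cytoplasmic vault particle. All 4 RNAs with a vault RNA symbol were called higher: VTRNA1-3 58.3-fold (log2 5.86, SE 1.27), VTRNA1-1 37.9-fold (log2 5.24, SE 1.05), VTRNA1-2 9.17-fold and VTRNA2-1 2.65-fold. The log2 value of VTRNA1-3 was 4.35 without exosome 5, 6.54 without exosome 3 and 6.53 without exosome 4. That of VTRNA1-1 was 4.25 without exosome 5, 5.84 without exosome 3 and 6.20 without cell 3. That of VTRNA1-2 was 3.85 without exosome 3 and 4.86 without cell 2.

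The counts for these lists were the same when adjusted over the list alone. Camera with a preset correlation called the Y RNAs (adjusted p = 0.00103) and the 7SL genes (adjusted p = 0.00317), and neither held with an estimated correlation (adjusted p = 0.488 for both). The vault list missed the threshold (adjusted p = 0.0583, and 0.498 with an estimated correlation). It passed with fry (0.0461), under total count scaling (0.0149), with near-identical features counted once (0.0395). It also passed without exosome 1 (0.0404), exosome 2 (0.0155), exosome 3 (0.0397), exosome 5 (0.0369) or cell 2 (0.0453). The call of VTRNA1-2 was lost without exosome 5 (log2 2.39, adjusted p = 0.0565), cell 1 (log2 2.60) or cell 3 (log2 3.27). That of VTRNA2-1 was lost without exosome 1 (adjusted p = 0.0752), exosome 5 (0.0667), cell 1 (0.16) or cell 2 (0.0847) and under total count scaling (log2 1.75, adjusted p = 0.0545).

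**Figure D2:**
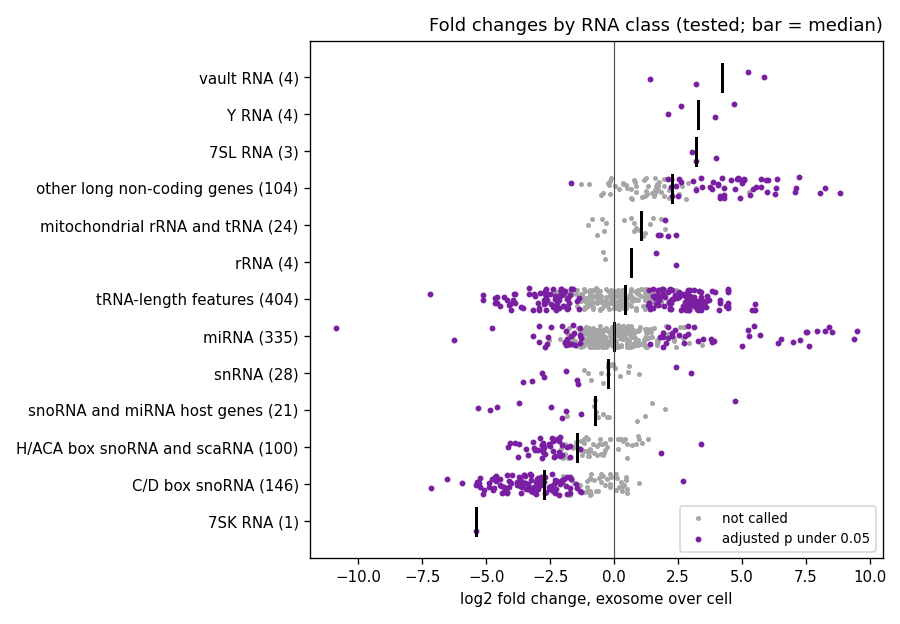
Log2 fold change of exosome over cell for each of 1178 tested features, grouped by RNA class with the number tested in brackets; purple points were called, grey points were not, and black bars are class medians. Medians were 3.29 for Y RNAs, 4.22 for vault RNAs, -2.73 for C/D box snoRNAs and -5.39 for the single 7SK gene; points of features without reads in a group depend on the fit's prior count.

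Small nucleolar RNAs fell in exosomes. Of 146 C/D box snoRNAs tested, 104 were lower, 1 was higher and 41 were not called, with a median log2 fold change of -2.73. SNORD101 (chromosome 6, 133136446 to 133136518) averaged 502 ± 116 CPM in exosomes and 46758 ± 7012 CPM in cells, a 93.2-fold difference (log2 -6.54, SE 0.53, adjusted p = 1.33e-06). SNORD88B (log2 -7.16), SNORD88C (-5.94), SNORD98 (-5.40), SNORD48 (-5.34), SNORD102 (-5.30), SNORD2 (-5.24), SNORD63 (-4.91) and SNORD18A (-4.03) fell as well. Without cell 2, SNORD88C was at -5.18, SNORD102 at -4.44, SNORD48 at -4.30 and SNORD18A at -3.05. Without cell 3, SNORD98 was at -4.59, and without exosome 4, SNORD88B was at -6.51, SNORD88C at -5.29 and SNORD102 at -4.71. RN7SK, a nuclear RNA that holds the transcription elongation factor P-TEFb inactive, was 42.0-fold lower (227 ± 38.9 against 9524 ± 8450 CPM, log2 -5.39, SE 0.71, adjusted p = 6.17e-05). The RN7SK feature is 331 nt long, also above the size limit of the input RNA, so its reads stand for fragments. The log2 value of RN7SK was -6.01 without cell 2 and -4.31 without cell 3. RN7SK took 0.055% of reads in cell 2 and 1.37% and 1.62% in the other cell libraries.

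Among the H/ACA box snoRNAs, which guide pseudouridylation, 33 of 82 were lower and 1 was higher, with SNORA64 at -4.08 (-3.48 without cell 3) and SNORA7A at -2.75 (-2.11 without exosome 4, -1.92 without cell 2). SNORA18 (-0.97) and SNORA34 (-0.15) were not called. Of 18 small Cajal body RNAs, which guide modification of snRNAs, 7 were lower and 1 higher. SCARNA9 was at -2.83, and SCARNA22 (-0.35), SCARNA12 (-0.54) and SCARNA20 (adjusted p = 0.152) were not called. Of 25 tested imprinted C/D snoRNAs, 5 were lower, among them SNORD116-25 (-3.23, and -2.25 without cell 3) and SNORD116-26 (-3.06, lost without cell 3 at -1.62), and SNORD116-8 (-1.06) and SNORD116-3 (-0.91) were not called. The host genes C17orf76-AS1 (-5.31), SNHG5 (-4.86) and GAS5 (-4.57), whose spans hold snoRNAs without an entry of their own, fell, SNHG5 by 2.59 without cell 2. The counted part covers 9.4% of the C17orf76-AS1 span and 12.4% of the SNHG5 span. Whether the counts of these host genes include the snoRNAs was not checked. GAS5 averaged 4465 ± 1466 CPM in exosomes and 106060 ± 21758 CPM in cells.

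Adjusted over the list alone, 107 C/D, 33 H/ACA and 7 Cajal body members were lower, and 3 of the imprinted list. Camera with a preset correlation called the C/D list (adjusted p = 2.36e-27), the H/ACA list (adjusted p = 7.21e-05) and the Cajal body list (adjusted p = 0.034), not the imprinted list (adjusted p = 0.302); with an estimated correlation the adjusted p was 0.488, 0.498, 0.498 and 0.819. The Cajal body call was also lost without exosome 4 (adjusted p = 0.0785) or cell 3 (adjusted p = 0.0556).

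Camera called neither list of spliceosomal snRNAs, and fry called the major list lower and the minor list higher (both adjusted p = 0.0461). Of 23 tested major snRNA features, 1 was higher, 7 were lower and 15 were not called (median log2 -0.22, camera adjusted p = 0.253, and 0.692 with an estimated correlation); adjusted over the list alone, 1 was higher and 5 were lower. RNU5E-1 was at -0.09, RNU5B-1 at -0.16, RNU5A-1 at -0.90 and RNVU1-18 at -0.22. Of the 4 snRNAs of the minor spliceosome, RNU11 rose 7.95-fold (409 ± 255 against 51.4 ± 21.7 CPM, log2 2.99, SE 0.67, adjusted p = 0.00235; log2 3.74 without cell 3), and RNU12 (0.98), RNU4ATAC (0.22) and RNU6ATAC (-1.02) were not called (list adjusted p = 0.342, and 0.501 with an estimated correlation). TERC, the telomerase RNA and the only member of its list in the tables, was at 0.21 (SE 0.55, adjusted p = 0.787). No Y RNA pseudogene had an entry.

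Of the 404 tRNA-length features tested, 129 were higher, 76 lower and 199 not called. With near-identical features counted once, 107 were higher and 69 lower of 357. The largest rise within the naming rule was in feature 23704 (chromosome 6, 26988125 to 26988218; 4.03 ± 1.78 against 0.0852 ± 0.0698 CPM, log2 5.50, SE 0.84, adjusted p = 0.000182; log2 6.21 without cell 1).

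Reads on the large rRNAs and on some mitochondrial RNAs were higher. The libraries were made from RNA under 200 nt, so reads on longer features stand for fragments. Features reach 5070 nt among rRNAs and 1559 nt among mitochondrial RNAs. RNA18S5 rose 5.31-fold (44999 ± 24918 against 8476 ± 3175 CPM, log2 2.41, adjusted p = 0.00615; log2 3.01 without exosome 4). RNA28S5 was 3.16-fold higher (log2 1.66, SE 0.64, adjusted p = 0.0472), a call lost without exosome 1 (log2 1.70), exosome 5 (0.91), cell 1 (1.41), cell 2 (1.44) or cell 3 (2.20). That call was also lost with limma-voom (1.225), with near-identical features counted once (1.74) and without exosome 5 and cell 2 together (0.81). RNA5-8S5 (-0.43) and RNA5S9 (-0.36), the 5S and 5.8S features with reads, were not called. Of 24 mitochondrial genes, 5 were higher and none lower (camera adjusted p = 0.0645, and 0.692 with an estimated correlation), and none was called when adjusted over the list alone. MT-TE, the tRNA for glutamate, was 5.38-fold higher (adjusted p = 0.0167, lost without cell 1 at log2 2.03). MT-RNR2, the large mitochondrial rRNA, was 3.98-fold higher (adjusted p = 0.0283, lost without exosome 2 at 1.70, cell 1 at 1.86 or cell 2 at 1.56, and at 2.84 without cell 3). Its call was also lost with limma-voom (1.58) and without exosome 5 and cell 2 together (1.67). MT-RNR1 (1.82) and MT-TF (-0.85) were not called. MT-RNR1 passed with DESeq2 (adjusted p = 0.0279), under total count (0.0397) and upper-quartile scaling (0.029), without the low-count filter (0.0105), at 50 counts in 3 libraries (0.0198), and without the large rRNA features (0.0302). It also passed without exosome 1 (2.15), exosome 3 (2.00), exosome 4 (2.33) or cell 3 (2.75). The list passed with near-identical features counted once (adjusted p = 0.0395) and without exosome 1 (adjusted p = 0.0195), exosome 4 (0.0331), exosome 5 (0.027) or cell 3 (0.00642). The mitochondrial share was 4.76% and 8.71% in exosomes 2 and 3 and 1.04% to 2.76% in the other exosome libraries.

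**Figure D3:**
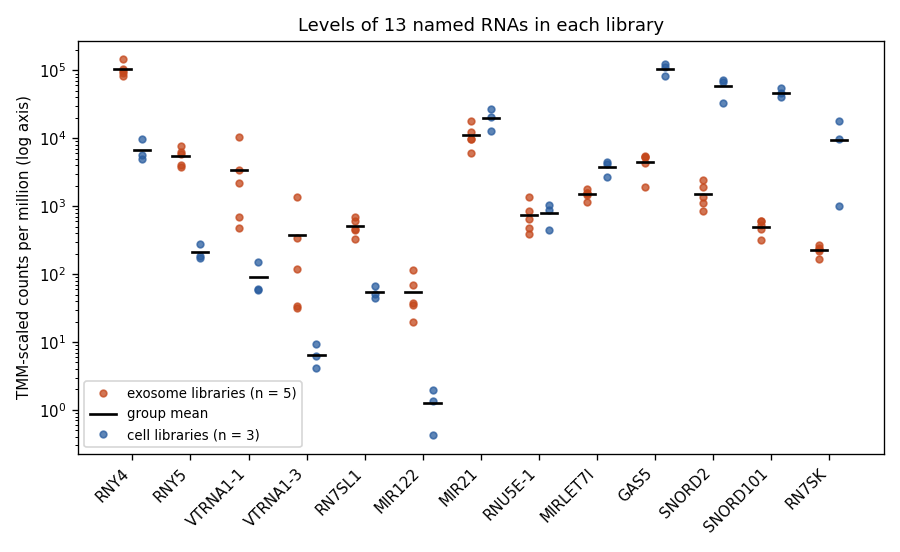
TMM-scaled CPM, on a log axis, of 13 named RNAs in each exosome library (orange, n = 5) and each cell library (blue, n = 3), with black bars at the group means. RNY4 averaged 103930 CPM in exosomes and 6743 CPM in cells, and SNORD101 averaged 502 and 46758 CPM.

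Most miRNAs were not called: 40 of 335 tested were higher in exosomes, 26 were lower and 269 did not pass. Of the 40 higher, 24 had a mean below 100 counts in exosome libraries and 8 had no read in any cell library. Of the 12 let-7 genes, a family of differentiation-linked miRNAs, 7 were lower and none higher (8 lower when adjusted over the list alone, and 2 lower, MIRLET7I and MIRLET7B, when miRNAs were compared alone). MIRLET7A1, MIRLET7A2 and MIRLET7A3 had nearly the same values (log2 -1.10, -1.12 and -1.11 with miRNAs alone), so the members are not independent. MIRLET7I averaged 1500 ± 220 CPM in exosomes and 3758 ± 945 CPM in cells (log2 -1.32, SE 0.46, adjusted p = 0.0283), and MIRLET7F2 (-0.82), MIRLET7F1 (-0.53) and MIRLET7G (0.14) were not called. None of the 11 B-cell and leukaemia-linked miRNAs was called by edgeR (0 at an unadjusted p under 0.05, and 0 called by DESeq2 or limma-voom), with MIR21, the most abundant, at -0.85 (11172 ± 4401 against 20177 ± 7015 CPM), MIR146B at -0.42, MIR181A1 at 0.32 and MIR181A2 at 0.11. None of 8 members of the miR-17-92 cluster and its paralogs was called either (1 at an unadjusted p under 0.05, and 0 called by DESeq2 or limma-voom), with MIR92A2 at -0.96, MIR25 at 0.61, MIR93 at 1.07 and MIR106B at 1.15. Of 6 miRNAs often found in vesicle preparations, 3 were higher, including MIR320B1 and MIR320B2 (both log2 2.10), whose counts were nearly the same, and MIR320A (1.21) and MIR150 (1.58) were not called.

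Some miRNAs of other tissues rose in exosomes. MIR122, the dominant miRNA of liver, was 44.2-fold higher in exosomes (55.3 ± 37.5 against 1.25 ± 0.790 CPM, log2 5.47, SE 0.85, adjusted p = 0.000194) and above the cell level in all 5 exosome libraries. MIR143, a smooth-muscle and stromal miRNA, was 14.8-fold higher (adjusted p = 0.00119), MIR126, of endothelium and platelets, 7.47-fold (adjusted p = 0.00559; log2 2.90, and 3.95 without cell 3), MIR203, of skin epithelium, 14.2-fold (adjusted p = 0.0173; log2 3.83, and 2.69 without exosome 5), MIR215 3.76-fold and MIR199B by a log2 of 2.54 (3.23 without cell 3). The red-cell miRNA MIR486 (0.86), the myeloid MIR223 (0.40), and MIR192 (0.61), MIR194-1 (0.71), MIR199A1 (1.90) and MIR199A2 (1.92) were not called. By list, 1 of 3 myeloid, platelet and red cell, 2 of 4 liver and gut, 1 of 7 epithelial and 2 of 4 stromal members were higher (4 stromal members when adjusted over the list alone), with MIR200B (-1.26), MIR200A (-0.71) and MIR200C (-0.08) not called. The tested muscle miRNA, MIR499A (-0.52), and both neural ones, MIR9-1 (-1.28) and MIR9-3 (-1.27), were not called; MIR208A, MIR1-1 and MIR208B had too few counts to be tested.

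Camera with a preset correlation called none of the miRNA lists: the adjusted p was 0.0679 for let-7, 0.0793 for the vesicle and the stromal lists, 0.088 for liver and gut, 0.253 for the myeloid list, 0.676 for the B-cell list, and 0.695 for the miR-17-92 and the epithelial lists. The call of MIRLET7I was lost under total count scaling (log2 -1.07) and without each exosome library or cell 3 (-1.35 to -0.96). The call of MIR215 was lost under total count scaling (2.01) and without exosome 1 or 5 or any cell library (1.63 to 2.28). It was also lost with limma-voom (1.61), without the low-count filter (2.12) and without exosome 5 and cell 2 together (1.49). The call of MIR203 was lost without cell 2 (3.08) or cell 3 (4.16), that of MIR199B without cell 1 (2.37) or cell 2 (2.27), and those of MIR320B1 and MIR320B2 without cell 1 (both adjusted p = 0.0709). MIR203 also lost its call with limma-voom (2.55) and without exosome 5 and cell 2 together (2.07). Calls were gained for MIR106B without exosome 3 (1.66), MIR320A without cell 3 (2.06), MIR150 without exosome 3 (2.09) or cell 3 (3.12), MIR200B without cell 2 (-1.67), and MIR199A1 (2.14) and MIR199A2 (2.16) without exosome 5. MIR106B also gained a call under upper-quartile scaling (1.49), at 50 counts in 3 libraries (1.59) and without the large rRNA features (1.48). At 50 counts in 3 libraries MIR320A passed (1.64), and without the low-count filter MIR150 did (1.71). With limma-voom MIR200B (-1.31), MIR9-1 (-1.60) and MIR9-3 (-1.61) passed, and with DESeq2 MIR199A2 (1.94). MIR200B also passed without exosome 5 and cell 2 together (-1.50). The let-7 list passed without cell 2 (adjusted p = 0.023) and the stromal list without exosome 5 (adjusted p = 0.0405).

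When miRNAs were compared alone, 36 of 368 were higher and 13 lower, and MIR199B (log2 2.86, adjusted p = 0.059) and MIR215 (2.00, adjusted p = 0.0831) were not called. Without exosome 4, 17 were higher and 11 lower; without cell 1, 11 and 13; without cell 2, 20 and 19; without cell 3, 18 and 36. MIR4420 (chromosome 1, 31212003 to 31212079) had no read in any exosome library and 723 in the cell libraries, at least 329-fold lower against a floor of 3 counts over the group. MIR4443 (-6.28, and -4.95 without cell 2) fell too, as did MIR3607 (-4.76, and -3.82 without cell 3) and MIR3687 (-2.95), 2 of the 5 miRNA entries that lie within other structured RNAs, of which MIR3609 (-0.21) and MIR4461 (0.07) were not called (list adjusted p = 0.159, and 0.498 with an estimated correlation).

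Among the 10 largest rises within the naming rule were 5 long non-coding genes, the 3 MIR3118 copies, VTRNA1-3 and feature 23704. Of 104 other long non-coding genes tested, 48 were higher in exosomes, 1 was lower and 55 were not called. RP11-343N15.1 (chromosome 1, 121102017 to 121140666) averaged 30.7 ± 27.1 CPM in exosomes and 0.0596 ± 0.0521 CPM in cells (log2 8.83, SE 1.43, adjusted p = 0.000265). TINCR, a non-coding RNA of epidermal differentiation, was 78.7-fold higher, LINC00174 61.6-fold and LINC00319 53.9-fold. Leaving out 1 library gave log2 values of 8.20 (cell 2), 9.44 (exosome 3) and 9.62 (cell 3) for RP11-343N15.1. For TINCR, at 6.30 with all libraries, they were 5.66 (cell 2), 5.70 (exosome 5), 6.90 (exosome 3) and 8.28 (cell 3). For LINC00174, at 5.94, they were 5.31 (cell 2) and 6.62 (cell 3), and for LINC00319, at 5.75, they were 5.14 (exosome 5) and 6.41 (cell 2). LINC00302 had 793 reads over the exosome libraries and 2 over the cell libraries, a ratio of 290.3 (95% interval 80.1 to 2402). MIR3118-1 had 891 and 2 (ratio 326, 95% interval 90.0 to 2698). MIR3118-3 had 806 and 3 reads (ratio 197, 95% interval 67.1 to 956), and MIR3118-2 was 156-fold higher (log2 7.28, and 6.65 without cell 1). Without 1 library the log2 value of MIR3118-3, 7.93 in the fit, was 7.32 (exosome 5 or cell 1) or 8.52 (exosome 3). All cell reads of LINC00302 and of the 3 MIR3118 copies came from cell 3. The class share overlapped between groups (0.076% ± 0.0329 against 0.0478% ± 0.0339, exact permutation p = 0.321, adjusted p = 0.348), and 35 of the 48 had a mean below 100 counts in exosome libraries.

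At equal depth, the number of RNA species was not called different. After thinning, 1538 ± 155 features were detected in exosome libraries and 1504 ± 163 in cell libraries (exact permutation p = 0.893, adjusted p = 0.964). The most abundant feature took 32.3% ± 11.4 of exosome reads and 16.3% ± 2.92 of cell reads (exact permutation p = 0.0357, adjusted over 3 measures p = 0.107). The 10 most abundant features took 74.3% ± 8.64 and 73.6% ± 2.51 (exact permutation p = 0.964, adjusted p = 0.964). With near-identical features counted once, the 10 most abundant differed by 8.87 percentage points (exact permutation p = 0.0357, adjusted p = 0.0536).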

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

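The tests on splits of the libraries, on scaling, length and nuclear RNA for snoRNAs, on serum for miRNAs, on scaling for MIR199B and MIR215 apart from the other miRNAs, and on outlying libraries by total counts were chosen after the result was seen. The test first written for scaling of those miRNAs, before its result was seen, took the loss of any call as a sign of scaling. Its condition was met, as 5 of 6 kept their call over 5 scalings and MIR215 did not, and the miRNAs were divided only after that. Of 119 values examined among the 5 exosome libraries, 13 had a library far from the other 4, where chance gives about 1 in 20.

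With TMM scaling, 11 of these values were levels of named RNAs, and by total counts 3 of the 11 stayed apart: SNORA34, MIR143 and MIR3609, all in exosome 3. The levels below carry the TMM factor, which was 0.524 in exosome 5 and raised its values. Exosome 5 had the lowest Y RNA share, 10.2% against 15.3% to 17.1% in the other exosome libraries, and the fewest features after thinning, 1265 against 1566 to 1635. It was the highest in RNA28S5 (981690 CPM against 165280 to 282640), RNA5-8S5 (345630 against 68493 to 105980), VTRNA1-3 (1370 against 31.9 to 336) and MIR203 (4.40 against 0.285 to 0.968); by total counts these were 514040 against 232550 to 341420, 180980 against 99980 to 149120, 717 against 34.7 to 406, and 2.31 against 0.309 to 1.41, none of them apart. Exosome 3 was the highest in SNORA34 (174 CPM against 54.0 to 60.4), SCARNA20 (45.8 against 19.7 to 23.2), MIR143 (26.9 against 3.22 to 7.55) and MIR3609 (36.3 against 8.13 to 15.5). Exosome 4 was the highest in the tRNA-length feature 23704 (7.13 CPM against 2.68 to 3.81) and the lowest in SNORD102 (98.3 against 254 to 284). Exosome 1 was the highest in RNU5B-1 (208 CPM against 143 to 158). Without exosome 5 and cell 2 together, 245 features were higher and 247 lower, and 418 of the 504 calls were made again.

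Whether the group difference could come from any grouping of the libraries was tested on the 56 splits of the 8 libraries into 5 and 3. The real split called 504 features and the highest other split 48, and 1 of 56 splits reached the real count. That other split set exosomes 1, 4 and 5 against the rest. For miRNAs alone the real split called 49 and the highest other split 0, with 1 of 56 reaching the real count. Every other split mixes exosome and cell libraries within a group, which widens the spread and leaves few calls. The counts of features and miRNAs therefore show that no other split did as much, and they cannot exclude chance between cultures. For the fixed lists under camera with a preset correlation, 29 of 56 splits called at least the 5 lists of the real split, and the highest other split called 9, so chance cannot be excluded for the number of lists.

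C/D box snoRNAs were low in exosomes while Y, vault and 7SL RNAs were high. The tables argue against scaling between libraries: over 5 scalings the median of the C/D snoRNAs was at most -2.28 and the lowest median of the other 3 classes was 3.22. Length of the feature alone is argued against as well, since within 79 to 127 nt the Y and vault RNAs lay 5.99 log2 units above 81 C/D snoRNAs. A loss of all nuclear RNA alike is argued against by 23 spliceosomal snRNAs, near-identical copies once. Their median of -0.43 (SD 1.62) lay above the C/D median of -2.73. However, RN7SK (-5.39, from reads of fragments), H/ACA snoRNAs (median -1.51), small Cajal body RNAs (median -1.33) and 7 of 23 major snRNA features were lower too. A loss of part of the nuclear RNA therefore stays open. Which ends and fragments the ligation kit captured, and sorting of cytoplasmic RNA into exosomes, stay open and were not tested.

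Of 104 long non-coding genes, 48 were called higher in exosomes and 55 were not called, while the class share overlapped between groups (exact permutation p = 0.321). Scaling is argued against, since the class median was at least 2.27 over 5 scalings. Background fragments spread along gene length, as from DNA or nuclear debris, may contribute: across the 48 called genes the mean exosome count rose with counted length (Spearman rho = 0.49 across genes, permutation p = 0.00055), but the cell counts of the class rose with length as well (rho = 0.457), so the relation is not specific to exosomes. Whether a single exosome library carried the rise stays open, since 30 of the 48 were still called without exosome 1, 31 without exosome 5, 33 without exosome 4, 44 without exosome 3 and 46 without exosome 2. Release of these RNAs in exosomes was not tested.

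Several miRNAs of other tissues were high in exosomes, among them MIR122, MIR126 and MIR143. By the test first written, scaling stays open for the set; divided afterwards, MIR122, MIR126, MIR143 and MIR203 were all 4 called under each of 6 scalings, the one from miRNAs alone included. The call of MIR199B ended with miRNAs alone (log2 2.54, SE 0.87, before and 2.86, SE 0.95, after) and that of MIR215 with miRNAs alone (1.91, SE 0.75, before and 2.00, SE 0.72, after) and under total count scaling (2.01), where adjusted p rose to 0.059, 0.0831 and 0.0972 although no log2 fold change fell, so both stay open. Calls were made for 6 of 21 tested members of 6 lists of other tissues against 34 of 314 other miRNAs (Fisher's exact p = 0.0275), and with miRNAs alone for 4 of 21 against 32 of 347 (p = 0.138), but the calls prompted this test, so RNA of serum or of other cells cannot be told apart from export by the line. The blood miRNAs MIR486 (28.3 ± 21.5 CPM in cells) and MIR223 (3.27 ± 2.81) were not called, which excludes nothing at these cell levels; export was not tested.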

How the results depend on the processing

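The runs with near-identical features counted once, without exosome 5 and cell 2, and without the large rRNA features were chosen after seeing the data. Counts of features stayed within 1.5 times of 241 higher and 263 lower under each alternative (173 to 325 higher, 184 to 283 lower), and of 56 called named genes 44 kept their call and direction in every alternative, with no reversal among the named genes; of all 504 calls 1 reversed sign without cell 2, and 1 without exosome 5 and cell 2. The labels do not say whether the replicate numbers pair the samples, and weak correlations of deviations between same-numbered libraries (0.102, -0.043 and 0.087) leave it open. Numbers 1 and 3 correlated best with their own number, number 2 did not. The run with the replicate number as a block also leaves out exosomes 4 and 5, so its changes cannot be put down to the block alone: 173 features were higher and 184 lower, against 183 and 216 in the same libraries without a block, 15 miRNAs were higher in place of 36, 5 lists were called higher in place of 2 (vault, adjusted p = 0.0484, mitochondrial, 0.00247, and stromal, 0.0436, besides Y and 7SL RNAs), and the Cajal body median was -1.23 without a call.

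Leaving out each library gave 11 to 34 miRNAs higher and 11 to 36 lower, and 2 to 5 lists higher; the Cajal body median ran from -1.79 to -0.74. Without exosome 5 and cell 2, 21 miRNAs and 5 lists were lower, and the host gene difference was -26.9 percentage points. With an estimated correlation 0 lists were called in either direction, at unchanged medians of 3.29 (Y RNAs), 3.22 (7SL), -2.73 (C/D), -1.51 (H/ACA) and -1.33 (Cajal body); fry called 8 higher (also vault, minor snRNA, vesicle, myeloid, liver and stromal) and 6 lower (also major snRNA, let-7 and structured RNA entries). The H/ACA median was -0.64 without cell 3. Without the most abundant feature of each library the differences in share were 0.144 (7SL), -27.7 (C/D), 20.6 (Y RNA), 9.54 (rRNA), 0.197 (snRNA), 23.4 (tRNA-length) and 0.698 (vault) percentage points. Counted once, they were 16.2 for Y RNA and 4.74 for tRNA-length features, the 10 most abundant features differed by 8.87 points (exact permutation p = 0.0357, adjusted p = 0.0536), and 4 lists were called higher. With features removed, shares are percentages of the remaining reads, so a class without removed reads gains share for that reason alone. Beyond this, the cause of the changes was not tested. Leaving out an exosome library allows no exact p under 0.0571, leaving out a cell library none under 0.0952, and 3 against 3 none under 0.1, so shares then stand as values only.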

Other observations

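The genes named here lie outside the rule for named genes and were chosen after their values were seen. Fisher's exact tests on the miR-320 copies (p = 1.3e-05) and the chromosome 14 cluster (p = 0.00306) were run after the calls were seen, and they decide nothing, since both groups were picked for their calls.

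Of 7 tested copies of miR-320, 6 were higher in exosomes, with a median log2 fold change of 2.27; some copies had nearly the same counts, so they are not independent. MIR320D1 was at 2.79 and MIR320C2 at 2.27. Of 10 tested miRNAs of the imprinted cluster on chromosome 14, 5 were higher, MIR379, MIR411, MIR412, MIR432 and MIR493, and none was lower; their mean levels stayed below 2 CPM in exosomes. On the other side, MIR128-1 (log2 -1.87) and MIR128-2 (-1.91), whose mature product is common to both, and MIR130B (-2.61, 15.9 ± 7.70 against 96.9 ± 34.5 CPM) were lower in exosomes.

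A few members ran against their class. SNORD89 was the only C/D box snoRNA called higher (71.4 ± 64.3 against 11.1 ± 5.29 CPM, log2 2.69, adjusted p = 0.0106), and SNORA81 (log2 3.39, adjusted p = 0.000272) and SCARNA7 (1.83, adjusted p = 0.0138) were the only H/ACA and Cajal body RNAs called higher. SNORA81 rose from 8.12 ± 1.64 CPM in cells to 85.1 ± 16.9 CPM in exosomes. Among tRNA-length features, counts higher and lower were 12 and 2 of 29 at 71 nt, 66 and 26 of 148 at 72 nt, 27 and 27 of 108 at 73 nt, 1 and 8 of 36 at 74 nt, 12 and 4 of 32 at 82 nt and 0 and 1 of 12 at 83 nt, with no order by length, and features with nearly the same counts are included several times.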
